A study of Mus musculus with 84 samples.

How the data were processed

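The series profiles single sensory neurons of the mouse vagal ganglia (strain C57BL/6) that had taken up the lipophilic tracer DiI (2%) by retrograde transport from the airways. Per the labels' protocols, each traced neuron was collected on its own, its mRNA was amplified, and the libraries were read on a NextSeq 500 with 76-base reads. The deposited table holds raw read counts, whole numbers for 50686 Ensembl mouse genes in 84 neurons, with no normalization. Per the submitters' processing notes, reads were assigned to genes with featureCounts, whose version is not given. The aligner, the genome build, the gene annotation and the strand setting used in counting are not given in the sources used here, and no molecular identifiers are mentioned, so amplified copies of a transcript count more than once.

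Each neuron is a separate sample and the labels define 1 group. No label names the animal a neuron came from, so neurons are not treated as replicates, no check between replicates exists, and no p-value or standard error was computed. Classes of neurons are compared by shares, medians and ratios, with quartiles over neurons as a description of spread. Shares of neurons are given with exact (Clopper-Pearson) 95% binomial intervals, and a share of 0 is given with the upper limit that 3 counts would set. These intervals and limits cover counting error only. Differences between classes are named by a fixed rule of size, 40 percentage points in the share of neurons.

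Gene identifiers were matched to symbols with GENCODE M21 (GRCm38), and 50376 of 50686 matched. The 310 unmatched identifiers held at most 0.253% of the counts of any neuron. Coordinates below are from that annotation, which need not be the one the authors used. CPM values (counts scaled to a sum of 1e6 per neuron) were computed from each neuron's total, and a gene was called detected at 10 CPM or more, which is 67.3 counts in the shallowest neuron kept. A neuron was left out when log10 of its total or its number of genes with a count lay more than 3 scaled median absolute deviations below the median of all 84. The limit on totals was about 4569950 counts and removed 12 neurons. The limit on gene number fell below 0 and removed none, so the filter worked on depth alone. No 2 neurons had identical counts, and the highest correlation of log2(CPM + 1) between 2 kept neurons was 0.959.

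Neurons were clustered on log2(CPM + 10). Genes had to reach 10 CPM in at least 5 neurons, and mitochondrial genes and all 241 genes of the fixed lists were left out, which left 11174 genes. The 1000 genes with the highest variance above the median of their bin (20 bins by mean) were centred, reduced to 10 principal components and clustered by Ward linkage. The number of clusters, from 2 to 8, was that with the highest mean silhouette among solutions whose smallest cluster held at least 5 neurons. The comparison of classes used the 2 largest clusters, called by number. Ganglion markers named here are Phox2a, P2rx2, Ntrk2 and Hoxb5 for the nodose and Prdm12, Prrxl1, Runx1 and Tac1 for the jugular ganglion. Planned results that rest on items withheld from this text, among them the naming of clusters by ganglion, are not reported here.

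The 25 gene lists (ganglion markers, neuron classes, channels, receptors, peptides, injury genes and markers of other cells), the rules above and the rule for named genes were fixed before the data were examined. That rule names all ganglion markers and, in each other list, the 2 members with the highest share of neurons and up to 4 members with the largest difference of 40 points or more between classes. Lists of 13 or fewer members could be named whole. Outside the lists it takes the 10 genes per class with the largest difference and the 5 genes with the highest median CPM. Of the list genes, 226 entered the count of differences, since ganglion markers and sex genes were left out of it. The comparison of Prdm12 neurons with other neurons and a second round of clustering inside the larger cluster were chosen after seeing the data.

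Neuron identifiers run in 3 blocks parted by gaps of more than 30 numbers, with 16, 11 and 57 neurons. The labels do not say that these are collection batches, and values are also given within blocks. Alternatives covered the detection threshold, the neuron filter, thinning to equal depth, scaling by trimmed mean of M-values (TMM) from edgeR 4.0.16 in R 4.3.3, the clustering settings, the size rule and leaving out each block. No edgeR test was run. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9, with seed 1.

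The steps were tested on simulated data drawn from the mean levels of the 40 neurons with most genes and the totals of all kept neurons, with a set of genes lowered in 1 class and 30026 genes in all. With 7 against 37 neurons, a difference of 40 points or more was found for 100% of the genes kept at 0.02 of their level, 87.9% of those kept at 0.1 and 33.3% of those kept at 0.25. It was also found for 1.32% of 13841 unchanged genes, against 0.0289% with 28 against 44 neurons. In both simulations the 2 simulated classes were recovered as 2 clusters without error. All neurons of a simulated class shared the same mean levels, without subtypes, and unchanged genes of low level were counted too.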

Results

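Airway-projecting vagal sensory neurons were profiled singly to learn which genes each carries. The vagal ganglia of the mouse join the nodose ganglion, whose neurons come from placodes, and the jugular ganglion, whose neurons come from the neural crest and express the transcription factor Prdm12. The 84 neurons form 1 group in the labels. Total counts per neuron ranged from 576966 to 20668832, with a median of about 11935800 and quartiles of about 9376843 and 14406000. The 72 neurons kept after the depth filter had at least 6732279 counts and a median of 5855.5 genes at 10 CPM or more, with a range from 841 to 8870. Over these neurons 16068 genes reached 10 CPM in at least 1 neuron and 52 did so in every neuron. All values below are for the kept neurons, at 10 CPM unless stated, and each share describes these neurons with counting error only.

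Most kept cells carried the transcripts of sensory neurons: 70 of 72 had 50% or more of the 10 pan-neuronal genes (97.2%, 90.3 to 99.7%). All 10 pan-neuronal genes were detected in at least 50% of neurons. Snap25, a synaptic vesicle fusion protein, and Stmn2, a regulator of axonal microtubules, were each found in 72 of 72 neurons (100%, 95% interval 95.01 to 100%), at median levels of 2075 and 5250 CPM. The genes with the highest median CPM were Tuba1a (12319), Tmsb4x (6366), mt-Rnr2 (5844), Stmn2 and Ywhag (5092). Neurofilament genes of myelinated fibres were also widespread, with Nefl in 71 and Nefh in 69 of 72 neurons, as was Prph, the peripherin of small-diameter neurons, in 72.

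The first question was how many traced neurons bear ganglion markers. Prdm12 (chromosome 2, 31640037 to 31655795, GRCm38) was detected in 7 of 72 neurons (9.72%, 95% interval 3.999 to 19.0%). It was a low transcript, from 22.04 to 87.0 CPM with a median of 46.9 CPM in these 7 neurons, and the highest value below the threshold was 9.13 CPM. Within the identifier blocks it was detected in 2 of 16, 0 of 11 and 5 of 45 kept neurons. At 1 count or more the share was 30.6%, and at 50 CPM it was 4.17%. In the 2 clusters described below, Prdm12 was detected in 7 of 44 neurons (15.9%, 6.64 to 30.1%) and 0 of 28 (limit 10.7%). The value of 9.13 CPM belonged to AM086, a neuron of the second cluster and of identifier block 2. AM072 and AM076, of the same cluster and block, had 3.41 and 2.40 CPM. The 0 of 28 and the 0 of 11 therefore depend on the 10 CPM threshold. Fewer genes were detected in the second of these clusters, so the share over all 72 neurons can be too low. The neurons counted as without Prdm12 can include some in which it was missed.

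Markers of the nodose ganglion had wide reach. Ntrk2, the receptor for brain-derived neurotrophic factor, was found in 59 neurons (81.9%), Hoxb5, a homeobox gene, in 53 (73.6%) and the ATP-gated channel P2rx2 in 39 (54.2%), while Phox2a was found in 5 (6.94%). Among jugular markers, Runx1 was found in 50 neurons (69.4%), Tac1, which encodes substance P, in 43 (59.7%) and Prrxl1 in 29 (40.3%).

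The second comparison, chosen after seeing the data, set the 7 neurons with Prdm12 against other neurons. All 7 lay in the larger of the 2 clusters described below, whose neurons had more genes detected, so values lead with the 37 other neurons of that cluster. These 37 were not even in genes detected. In the second round of clustering below, 26 of them had a median of 7995.5 genes at 10 CPM and 11 had 5885, against 8091 in the Prdm12 neurons. Htr1b, an inhibitory serotonin receptor, was found in 7 of 7 Prdm12 neurons (100%, 59.0 to 100%) against 1 of 37, and in 1 of all 65 other neurons (1.54%, 0.0389 to 8.28%). Asic3, an acid-sensing channel, was found in 7 of 7 against 7 of 37, at a median of 293.8 CPM in the Prdm12 neurons. Piezo2, the stretch-gated channel of touch and lung inflation, was found in 7 of 7 against 17 of 37, at a median of 439.6 CPM in the Prdm12 neurons. In the other direction, P2rx2, Hoxb5, P2ry1 and Gfra2 were more frequent in the other neurons.

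Of the 226 list genes compared, 14 differed by 40 points or more within cluster 1, 11 with the higher share in Prdm12 neurons and 3 with the lower. The share over all genes is not given for the Prdm12 comparisons, so such counts cannot be called particular to the lists. Among mechanically gated and acid-sensing channels, Asic3, Piezo2 and Asic2 were higher, the last in 7 of 7 against 21 of 37. Among the 12 neuropeptides, Calca and Calcb, which encode calcitonin gene-related peptides, were higher: Calca in 5 of 7 (71.4%) against 8 of 37, at a median of 3888 CPM in the Prdm12 neurons, and Calcb in 4 of 7 against 4 of 37. The sodium channel subunit Scn4b was found in 6 of 7 against 9 of 37, the vesicular glutamate transporter Slc17a7 in 4 of 7 against 3 of 37 and the nucleotide receptor P2ry2 in 7 of 7 against 18 of 37. Ifngr1, an interferon gamma receptor subunit, was found in 5 of 7 against 11 of 37. Foxj1, listed as a marker of ciliated epithelium, was found in 6 of 7 against 5 of 37 at a median of 19.1 CPM in the Prdm12 neurons.

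Lower in Prdm12 neurons were the purinergic receptor P2ry1 (2 of 7 against 29 of 37), Gfra2, a co-receptor for neurturin (0 of 7 against 25 of 37), and Cckar, the cholecystokinin receptor (0 of 7 against 19 of 37). Against all 65 other neurons 27 list genes differed by 40 points or more, 25 of them higher in Prdm12 neurons and 2, Gfra2 and Cckar, lower. The genes added there included Pou4f1, Scn8a, Scn10a, Scn11a, Nmb, Tmem63b and Cnr1, each in 7 of 7 Prdm12 neurons. These 7 genes did not pass 40 points within cluster 1, where 29, 32, 30, 31, 28, 30 and 34 of the 37 other neurons had them, so their gaps to all others include the low shares of cluster 2. Some of these directions turned with the threshold: the difference (Prdm12 minus other neurons) was 13.8 points for Cckar at 1 count, and -10.8 points for Tmem63b and -4.62 points for Ifngr1 at 50 CPM. No TRP channel, injury gene or satellite glia gene passed 40 points in either comparison. The summed level of the satellite glia genes had a median of 294.7 CPM in Prdm12 neurons (quartiles 175.3 and 1464). In the 65 others it was 1440 CPM (251.9 and 2679). In all 44 neurons of cluster 1, the Prdm12 neurons included, it was 558.5 CPM (163.1 and 2124). The gap to the 65 others therefore includes the higher level of cluster 2, with a median of 1780 CPM. Trpv1, the capsaicin receptor, was found in 2 of 7 Prdm12 neurons (28.6%, 3.67 to 71.0%) and 17 of 65 other neurons (26.2%, 16.03 to 38.5%). Trpa1, the irritant receptor, was found in 0 of 7 and 13 of 65, and with 7 neurons a share of up to 42.9% could not be excluded. Over all 44 neurons of cluster 1, Trpv1 was found in 15 and Trpa1 in 9.

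The other ganglion markers differed in part. P2rx2 was found in 0 of 7 Prdm12 neurons and 39 of 65 other neurons, Hoxb5 in 1 of 7 and 52 of 65, and Ntrk2 in 3 of 7 and 56 of 65. Prrxl1 was found in 7 of 7 and 22 of 65. Phox2a (0 of 7 and 5 of 65), Runx1 (5 of 7 and 45 of 65) and Tac1 (3 of 7 and 40 of 65) did not differ by 40 points. Among the 37 other neurons of cluster 1, Ntrk2 was found in 37, Runx1 in 35 and Tac1 in 24. There Runx1 and Tac1, both listed as jugular markers, were less frequent in the Prdm12 neurons, by less than 40 points.

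**Figure D1:**
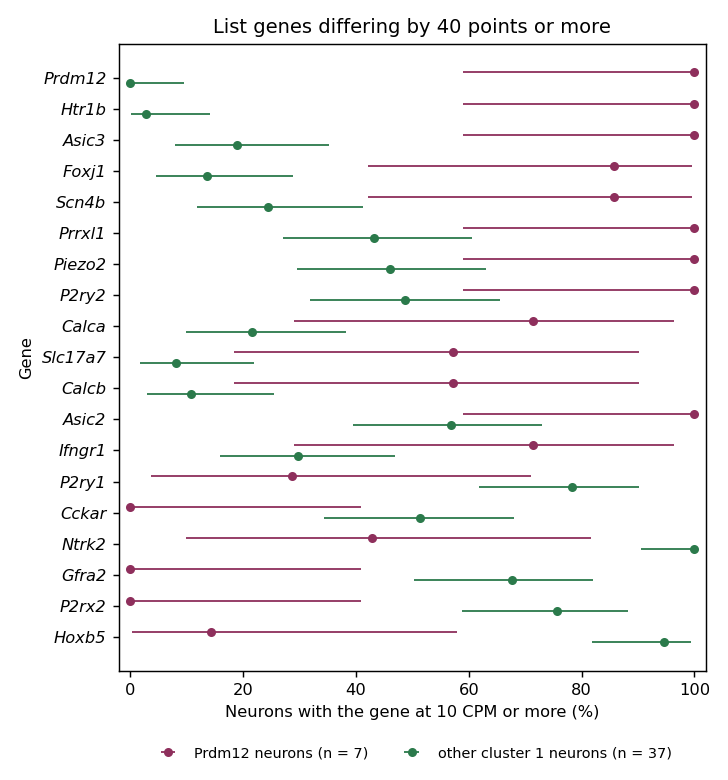
Share of neurons (horizontal axis, %) with each gene (vertical axis) at 10 CPM or more in the 7 neurons with Prdm12 and the 37 other neurons of cluster 1; points are shares and bars are exact 95% binomial intervals, which cover counting error only. The genes shown were chosen because they differ by 40 points or more. They include Prdm12, whose difference is fixed because it defines the classes, and other ganglion markers, which the count of list genes in the text leaves out.

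Outside the lists, genes that set the Prdm12 neurons apart from the 65 others are given as descriptors. On the Prdm12 side they were Gm13425, Gm43154, Trappc3l, Serpinb8, Syt6, Tmem28, Pou4f3, Syne4, Inka2 and Stk32c, each in 7 of 7 neurons. Pou4f3, a POU-domain transcription factor, was found in 6 of 65 other neurons. On the other side they were Dcdc2a, Fxyd6, Gm14336, Spon1, Fhod3, Samd5, Crip1, Rpl5 and Rasgrp1, each at 10 CPM in 0 of 7 Prdm12 neurons. Rpl5 and Gm14336 lay near the threshold on both sides, with medians of 5.65 CPM in Prdm12 neurons and 11.8 CPM in others for Rpl5, and 5.84 and 13.1 CPM for Gm14336. Dcdc2a, a doublecortin-domain gene, was found in 44 of 65 other neurons, at medians of 1.90 and 96.8 CPM.

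The 7 Prdm12 neurons limit every share in this comparison, and the simulation found 1.32% of unchanged genes past 40 points at 7 against 37 neurons. The simulated neurons had no subtypes and that rate counts genes of low level. It can therefore be too low for genes found in part of the neurons. Prdm12 neurons were also set against other neurons of the same identifier block. Htr1b was found in 5 of 5 against 0 of 40 in block 3 and 2 of 2 against 1 of 14 in block 1. Piezo2 was found in 5 of 5 against 12 of 40 and 2 of 2 against 7 of 14. The 40 and 14 include 16 and 5 neurons of cluster 2, where fewer genes were detected. Block 2 held no neuron with Prdm12 at 10 CPM. Some genes overlap others in GENCODE M21, and reads cannot be parted where counting ignored strand: Gm13425 is antisense to Prdm12, Htr1b overlaps D430036J16Rik, and Hoxb5 overlaps Hoxb5os.

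The third question was whether the neurons fall into types when the list genes play no part. Clustering gave 2 clusters, of 44 and 28 neurons (mean silhouette 0.353), and the first principal component held 23.9% of the variance. All 7 Prdm12 neurons lay in cluster 1. Markers of each ganglion were spread over both clusters: Ntrk2 was found in 40 of 44 and 19 of 28 neurons, Hoxb5 in 36 and 17, P2rx2 in 28 and 11, Tac1 in 27 and 16, Prrxl1 in 23 and 6, and Runx1 in 40 and 10. The clusters are therefore called by number.

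The clusters differed in how many genes were detected. The median number of genes at 10 CPM was 7802.5 in cluster 1 and 3026.5 in cluster 2, at median totals of about 13976400 and 11456150 counts. Outside the mitochondrial genes, 5940 genes had a share at least 40 points higher in cluster 1, and 9 had one at least 40 points higher in cluster 2. For comparison, 16068 genes reached 10 CPM in at least 1 kept neuron. Of the 226 list genes, 42 differed by 40 points or more, and all 42 had the higher share in cluster 1. These 42 are part of that general difference and not a result particular to the lists. They included 6 of 13 sodium channel genes (Scn8a in 39 of 44 against 6 of 28, Scn10a in 37 against 7), 4 of 15 inhibitory receptors (Cnr1, the cannabinoid receptor, in 41 of 44 against 3 of 28) and 3 of 13 TRP channels (Trpv2 in 37 of 44 against 1 of 28). They also included 6 of 21 inflammatory mediator receptors (Ptger4, a prostaglandin E2 receptor, in 34 of 44 against 2 of 28) and 5 of 28 cytokine receptors (Ifngr2 in 42 of 44 against 6 of 28). The other lists gave 4 of 12 mechanically gated and acid-sensing channels (Tmem63b in 37 of 44 against 3 of 28), 3 each of the pan-neuronal, A-fibre, C-fibre, P2X and P2Y and neurotrophic receptor lists, 2 injury genes and 1 neuropeptide gene, with some genes in more than 1 list.

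None of the serotonin receptors, gut-associated genes, satellite glia, Schwann cell, endothelial, fibroblast, leukocyte, erythrocyte or epithelial genes passed 40 points between clusters. The summed level of the 10 pan-neuronal genes had a median of 12309 CPM in cluster 1 (quartiles 11279 and 15390) and 10210 CPM in cluster 2 (6098 and 13981). The summed level of the 7 satellite glia genes had medians of 558.5 CPM (163.1 and 2124) and 1780 CPM (1169 and 5571). After thinning every kept neuron to 6732279 counts, the median numbers of genes with a count were 13804 and 8222. When the same clustering was scaled with TMM factors, no allowed number of clusters remained.

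**Figure D2:**
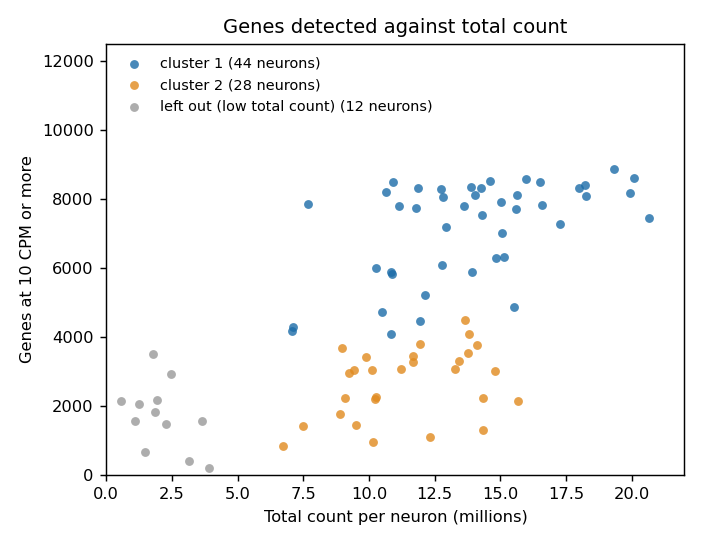
Number of genes at 10 CPM or more (vertical axis) against the total count (horizontal axis) for each of the 84 neurons (points); colours mark cluster 1, cluster 2 and the 12 neurons left out for low totals. Clusters 1 and 2 overlap in total count, while gene numbers run from 4088 to 8870 in cluster 1 and from 841 to 4500 in cluster 2.

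A second round inside cluster 1, chosen after seeing the data, placed the 7 Prdm12 neurons by themselves. With 3 clusters the sizes were 26, 11 and 7, and the cluster of 7 held every Prdm12 neuron, with Prrxl1 in 7 of 7, Hoxb5 in 1 and P2rx2 in 0. The cluster of 11 had Ntrk2 in 11 of 11 neurons, Hoxb5 in 9 and P2rx2 in 8, with Prrxl1 in 2. The cluster of 26 had Ntrk2, Hoxb5 and Runx1 in every neuron and Prrxl1 in 14. For each of the 7 Prdm12 neurons the nearest neighbour in the 10 components was another Prdm12 neuron, where 13.95% of the other cluster 1 neurons had Prdm12. The silhouette rule itself gave 2 clusters in this round, of 33 and 11 neurons, so 3 clusters was a choice of resolution.

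Lists for receptors and channels were described over all 72 neurons. Of 13 TRP channels 9 were detected in at least 1 neuron, led by Trpv2 and Trpm7 (38 neurons each, 52.8%). Trpv1 was found in 19 neurons (26.4%, 16.7 to 38.1%) and Trpa1 in 13 (18.1%, 9.98 to 28.9%), while Trpv4, Trpm8, Trpc5 and Trpc6 were found in none. Of 11 P2X and P2Y receptors 10 were detected, led by P2ry1 (43 neurons, 59.7%) and P2rx2. P2rx3, the other subunit of sensory ATP-gated channels, was found in 27 neurons (37.5%) at a median of 7.07 CPM, and it overlaps Ssrp1 on the other strand, so its level is uncertain. All 12 mechanically gated and acid-sensing channels were detected, led by Tmem63b and Kcnk2 (40 neurons each, 55.6%), and Piezo2 was found in 34 neurons (47.2%).

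Sodium channels were the most widely shared channel list, with 13 of 13 detected and 7 in at least 50% of neurons, led by Scn7a (64 neurons, 88.9%) and Scn9a (57 neurons, 79.2%). Scn10a and Scn11a, the tetrodotoxin-resistant channels of nociceptors, were found in 44 and 46 neurons. Of 8 C-fibre nociceptor genes 3 reached 50% of neurons, and of 12 A-fibre genes 6 did so. Neurotrophic factor receptors (9 of 10 detected) were led by Ret (62 neurons, 86.1%) and Ntrk2. The 12 neuropeptides were all detected, with Tac1, Adcyap1 and Nmb in 43 neurons each and Calca in 25. Serotonin receptors (8 of 12) were led by the ion channel subunits Htr3a (34 neurons, 47.2%) and Htr3b (18 neurons, 25%).

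Inflammatory mediator receptors (17 of 21 detected) were led by the adenosine receptor Adora1 (53 neurons, 73.6%) and S1pr3 (46 neurons, 63.9%). Bdkrb2, Cysltr1, F2rl1 and Adora2b, named after their values were seen, reached 10 CPM in no neuron. Inhibitory receptors (13 of 15) were led by the GABA-B subunits Gabbr1 (58 neurons, 80.6%) and Gabbr2 (50 neurons, 69.4%). Cytokine and innate immune receptors (23 of 28) were led by Lifr (57 neurons, 79.2%) and Il6st (52 neurons, 72.2%), the receptor subunits for leukaemia inhibitory factor and related cytokines. Of 11 genes associated with gut or cardiovascular vagal neurons 8 were detected, led by Cckar (30 neurons, 41.7%) and Sst (8 neurons, 11.1%), while Glp1r, Ghsr and Lepr were found in none. Each share of 0 of 72 allows up to 4.17%.

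Injury and stress genes were abundant. All 12 were detected and 10 reached 50% of neurons, led by Gap43 (71 neurons, 98.6%) and Egr1 (69 neurons, 95.8%), and Atf3, a transcription factor induced by axon injury, was found in 67 (93.1%). Markers of cells beside the neuron were also found. Satellite glia genes (7 of 7 detected) were led by Glul (63 neurons, 87.5%) and Apoe (55 neurons, 76.4%), and Schwann cell genes (5 of 6) by Pmp22 (62 neurons, 86.1%) and Mbp (48 neurons, 66.7%). No gene of the other cell lists reached 50%: the highest shares were Col1a2 for fibroblasts (34 neurons, 47.2%) and Dcn (22 neurons), Hba-a2 for erythrocytes (18 neurons) and Hba-a1 (8), Flt1 for endothelium (11 neurons) and Cldn5 (3), and Cd68 for leukocytes (4 neurons) and Lyz2 (3). Of the airway epithelium genes Foxj1 was detected in 12 neurons, and Sftpc, Sftpa1, Scgb1a1 and Epcam in none.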

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

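The tests of read depth, of random loss, of a gene programme and of glial RNA, and the choice of genes for the neurons left out, were made after the results they bear on were seen. The 12 neurons left out for low total counts entered no share or comparison of the report. Calca was detected in 6 of these 12 (95% interval 21.1 to 78.9%), but 4 of the 6 lay near the threshold, at 12.2 to 23.8 CPM, and AM301 and AM290 had 93.9 and 325.9 CPM. Piezo2 was detected in 4 of 12 (33.3%, 9.92 to 65.1%), from 62.3 to 424.8 CPM. Prdm12 was detected in 0 of these 12, and 11 of the 12 had at least 5 of the 10 pan-neuronal genes. Neuron AM214, with 78.2% of its counts from mitochondrial genes, had the fewest genes with a count, 2774.

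Neurons of cluster 2 had fewer genes detected than those of cluster 1, and the labels give no groups with which to test a biological explanation. Lower read depth is excluded as the whole cause: with every neuron thinned to the same total, the median number of genes with a count was 8222 in cluster 2 (upper quartile 9257) and 13804 in cluster 1 (lower quartile 11574), a ratio of 0.596. Random loss of transcripts in capture or amplification, which should keep the mean CPM of a gene over all neurons, stays open. It was tested on 7343 genes found in at least 50% of cluster 1 neurons. The 2447 with the lowest means kept 0.925 of their summed mean CPM (quartiles over cluster 2 neurons 0.837 and 0.983), though the median gene kept 0.546. The sums for genes of middle and high level were 0.951 and 0.984 of those in cluster 1. A sum can be carried by a few genes, and CPM has the same total in every neuron, so this test cannot single out random loss. A gene programme switched off in all of these neurons stays open, since of the 5940 genes with a share at least 40 points higher in cluster 1, 1233 (20.8%) were found in fewer than 10% of cluster 2 neurons, for example Klhl26 and Mgat5 in 0 of 28. Replacement of neuronal RNA by RNA of other cells stays open too, since the summed pan-neuronal CPM of cluster 2 was 0.829 of that of cluster 1 with quartiles from 0.495 to 1.14, wide enough to span both bounds set for this test; its label was made to depend on the quartiles after the value was seen.

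Satellite glia transcripts were found in most neurons. If glial RNA was collected with the neuron, glial genes should occur together in the same samples. At least 2 of Fabp7, Kcnj10, Sox10 and Cdh19 were detected in 27 of 55 neurons with Apoe and in 0 of 17 without it, a difference of 49.1 points. Fabp7 alone was found in 49 of 55 and 3 of 17, and Sox10 in 18 of 55 and 0 of 17. These values are consistent with glial RNA collected with the neuron, and expression of these genes by the neurons was not tested.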

How the results depend on the processing

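The second round of clustering and the comparisons of Prdm12 neurons with other neurons were chosen after seeing the data. With the detection threshold at 1 count, Prdm12 was found in 30.6% of neurons, at 50 CPM in 4.17% (3 of 72), and under the other 9 alternatives in 7.41 to 15.9%. The number of neurons kept was 72 with 2 median absolute deviations and 84 with no filter. All 13 clusterings with a value gave 2 or 3 clusters, and TMM scaling gave none because no solution had at least 5 neurons in its smallest cluster. The count of 42 list genes between clusters became 20 at 1 count, 23 at 50 CPM and 21 at 50 points, and it lay between 33 and 56 under the other settings. With Prdm12 neurons against all other neurons the count was 27, and against the other neurons of cluster 1 it was 14. Of 35 genes compared between Prdm12 and all other neurons, 28 were reversed under no alternative, and the cause of the other changes was not tested. Apart from ganglion markers, these genes were taken because they had passed the size rule in these same data. A gene picked for a large difference is less likely to change sign, so the 28 are not separate evidence of stability. At 1 count the difference (Prdm12 minus other neurons) became 13.8 points for Cckar and 1.54 points for Tac1. At 50 CPM it became -10.8 points for Tmem63b and for Lpar3, -4.62 points for Ifngr1 and -26.8 points for Runx1. With TMM scaling it became -6.15 points for Ifnar1 and -12.1 points for Runx1. Runx1, whose main difference was 2.2 points, also became -23.2 points in cluster 1 alone and -26.0 points without block 3 of the identifiers. No paired analysis was possible because the labels define 1 group.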

Other observations

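The gene pairs, genes and neurons below were chosen after seeing the data. Each pair is given over the 72 kept neurons and within cluster 1, whose neurons had more genes detected. Trpv1 and Trpa1 were found together: Trpa1 in 10 of the 19 neurons with Trpv1 (52.6%, 95% interval 28.9 to 75.6%) and in 3 of the 53 without it (5.66%, 1.18 to 15.7%), and within cluster 1 in 8 of 15 and 1 of 29. P2ry1 was found in 8 of the 19 neurons with Trpv1 (20.3 to 66.5%) and in 66.0% of those without it (51.7 to 78.5%), intervals that overlap, and within cluster 1 in 6 of 15 (16.3 to 67.7%) and 25 of 29 (86.2%, 68.3 to 96.1%), intervals that do not. Npy2r was found in 10 of 19 and 30.2%, within cluster 1 in 9 of 15 and 48.3%, and Piezo2 in 8 of 19 and 49.1%, within cluster 1 in 6 of 15 and 62.1%, with intervals that overlap in each case. P2rx3 was found in 20 of the 39 neurons with P2rx2 (51.3%, 34.8 to 67.6%) and in 7 of the 33 without it (21.2%, 8.98 to 38.9%). Within cluster 1 it was found in 18 of 28 (44.1 to 81.4%) and 37.5% (15.2 to 64.6%), and the intervals overlap in both sets. All these intervals cover counting error only, so their overlap or lack of it is a description and not a test of a difference.

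The Prdm12 neurons had high levels of some genes that other neurons also carried. Nefh had a median of 2584 CPM in the 7 Prdm12 neurons (quartiles 2338 and 3546), 817.5 CPM in the 37 other neurons of cluster 1 (452.5 and 1334) and 592.2 CPM in all 65 other neurons (196.5 and 1239). Nmb, which encodes the peptide neuromedin B, had medians of 519.8 CPM (431.6 and 755.4), 32.5 CPM (12.97 and 86.5) and 16.7 CPM (0.894 and 58.9) in the same sets, and 28 of the 37 other cluster 1 neurons had it. Foxj1 was detected in 6 of 7 Prdm12 neurons while Sftpc, Sftpa1, Scgb1a1 and Epcam were detected in none of the 72 neurons.

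Of the 10 genes outside the lists that most set cluster 2 apart, 8 (Gm10720, Gm11168, Gm10715, Gm17535, Gm10718, Gm10722, Gm26870 and Gm10719) lie on chromosome 9 between 3000282 and 3038316 (GRCm38), at the start of its assembled sequence. Their summed level had a median of 30.3 CPM in cluster 1 (quartiles 13.5 and 148.3), 925.7 CPM in cluster 2 (227.1 and 2441) and 13981 CPM in the 12 neurons left out for low totals. Of these 8, all genes other than Gm26870 overlap Gm26870 on the other strand, so the 8 describe 1 locus. What its level reflects was not tested. On the other side, Usp13, Mta1, Klhl26, Mgat5, Snrpd3, Ube2g1, C78859, Nudt10, Cse1l and Ppfia4 most set cluster 1 apart, with Usp13 in 44 of 44 against 2 of 28 neurons.

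In 4 of the 5 kept neurons with the lowest summed level of pan-neuronal genes, the satellite glia genes had the higher sum. AM244 had a summed pan-neuronal level of 291.3 CPM and 35386 CPM for the satellite glia genes, and AM287 had 2991 and 56618 CPM, with Apoe at 33719 CPM.

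Among the kept neurons, sex-linked genes followed the identifier blocks. A Y-linked gene (Ddx3y, Uty, Kdm5d or Eif2s3y) was detected in 2 of 16 kept neurons of the first block, 2 of 11 of the second and 36 of 45 of the third (80.0%, 65.4 to 90.4%). Xist was detected in 7, 3 and 0 of these neurons, and no kept neuron had Xist together with a Y-linked gene. Of the neurons left out for low totals, AM294 of the third block had both, with Xist at 16483 CPM and Kdm5d at 13.9 CPM. Of the 7 Prdm12 neurons 5 had a Y-linked gene and 2 had Xist. The labels used here give no sex.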
